A study of Mus musculus with 6 samples.

How the data were processed

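Liver RNA of 6 mouse samples was measured by bulk RNA sequencing, 3 libraries labelled wild-type (WT) and 3 labelled Atg14 HepKO (HepKO from here on). Per the labels' protocols, total RNA was purified from liver tissue with a column kit and polyA RNA was made into libraries with a stranded mRNA kit. The labels do not say that the 3 samples of a group came from separate animals, so p-values measure the spread between these samples. Age, sex, diet, time of collection and the Cre line are not given in the sources used here.

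The deposited values were raw read counts per gene, made by the authors. Per the submitters' processing notes, bcl2fastq, STAR 2.7.11a, featureCounts from Subread 2.0.0 and edgeR 3.40.2 were used with the mm10 build, and the notes give no order or settings. The annotation release and the strand setting of the counting are not given in the sources used here. A gene and an antisense or overlapping partner therefore could not be told apart, and reads of near-identical copies could have been split or dropped. Values of multigene families (Mup, Cyp2a, Cyp2c, Cyp3a, Cyp4a, Gsta, Gstm, Serpinb, H2 and the haemoglobin genes) are uncertain for that reason. The table held 56350 versioned Ensembl mouse gene IDs, of which 55480 matched GENCODE M21 (GRCm38, the same assembly as mm10) and 55180 also matched in version. The other 870 IDs had no symbol and kept their ID, and held at most 0.00572% of a library's counts.

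Some genes that most cells express had almost no counts in any library. Among the fixed lists, the highest count in a library was 9 for Uqcrc1, 4 for Nrbf2, 3 for Atg2a, 1 for Kif11 and 0 for Atg4a. The cause was not established, and a count near 0 was not read as absence of the transcript.

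Total counts were 35720011, 41754560 and 41464638 in WT replicates 1 to 3, and 48951937, 37265058 and 33145684 in HepKO replicates 1 to 3. Pairs of libraries within a group differed by far more than sampling noise (chi-square per degree of freedom 27.1 to 137), so none was treated as a repeat of another. Genes were filtered with filterByExpr by group, which kept 16051 genes. Counts were scaled with the trimmed mean of M-values (TMM), whose factors were 0.829, 0.860 and 0.824 in WT and 1.19, 1.21 and 1.19 in HepKO. All CPM values use the TMM-scaled library totals.

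HepKO was compared with WT by the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, 2-sided, with no covariate. Genes were called at a Benjamini-Hochberg adjusted p (FDR) under 0.05. The standard error of a log2 fold change (log2FC, HepKO over WT) was its size over the square root of the F statistic. Values after ± are SE for log2 fold changes and SD over 3 libraries for CPM. Where 3 counts or fewer were found in a group, the fold was given against a floor of 3 counts over the group, or as a ratio with a 95% counting interval, which covers counting error only.

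A set of 44 gene lists was fixed before the data were examined. Each list with at least 3 tested members was tested with camera (limma 3.58.1, preset correlation 0.01 between genes), adjusted over the 42 lists tested, and again with an estimated correlation and with fry. A list was called at a camera FDR under 0.05. Camera compares a list with all other genes, while fry asks whether its genes move one way on balance. The naming rule was also fixed before the data were examined. It took Atg14, the 12 genes with the highest and the 12 with the lowest log2 fold change, and the 3 tested members of each list with the smallest p. The 24 genes of extreme fold had to have an FDR under 0.05, a mean of at least 5 CPM over the 6 libraries and no overlap between the groups. Predicted genes, Rik clones, pseudogenes and IDs without a symbol were left out of those 24. Not every gene taken by the rule is given in the text. Any other gene named was chosen after its values were seen.

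Alternatives fixed in advance were DESeq2 1.42.0, limma-voom, median-of-ratios (RLE) factors, library totals without scaling factors, scaling without the 20 most abundant genes, a filter of at least 1 CPM in 3 libraries, and no filter. Leaving out each library, the replicate number as a block, an FDR of 0.01 and an absolute log2 fold change of at least 1 were also run. TMM and library totals differed throughout: the median log2 fold change of tested genes was 0.01 under TMM and 0.52 under library totals, so every fold is relative to that scaling. Gene families sharing a symbol stem were tested after the list results were seen.

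The test was tried on counts simulated from the means and library sizes of these libraries, with 15501 of 16051 simulated genes tested. Of genes changed 4-fold, 63.3% of 60 were recovered, as were 40.3% of 67 changed 2-fold and 1.52% of 66 changed 1.5-fold. At 5 CPM or more, 93.5% of 31 genes changed 4-fold were recovered. Of 69 calls, 3 were false. Far fewer genes were changed in the simulation than were called in the data (6131), so its adjusted threshold demanded smaller p-values. The recovery rates therefore do not give the power of the comparison of HepKO with WT.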

Results

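The series measured gene expression in mouse liver, in 3 WT and 3 HepKO samples, to compare the liver transcriptome with and without a targeted Atg14 gene. Atg14 encodes a subunit of the lipid kinase complex that starts autophagosome formation. Total counts per library ranged from 33145684 to 48951937 reads assigned to genes, and 19540 to 24321 genes had at least 1 count. Mitochondrial genes took 7.43% to 9.36% of the counts, with no separation of the groups. The 10 most abundant genes took 20.3% to 23.1% of the counts in WT and 14.8% to 15.9% in HepKO, and albumin (Alb) alone took 5.67% to 7.48% in WT and 3.50% to 4.32% in HepKO. Correlations of log2 CPM across genes were 0.965 to 0.981 within groups and 0.896 to 0.931 between them. The first principal component held 67.1% of the variance and separated the groups.

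Atg14 mRNA was lower in all 3 HepKO libraries than in any WT library. Atg14 (ENSMUSG00000037526.7) is a protein-coding gene on the minus strand of chromosome 14, from 47540893 to 47570649 in GRCm38 (mm10). It had 620, 796 and 719 counts in WT replicates 1 to 3. In HepKO replicates 1 to 3 it had 329, 379 and 313 counts. The means were 21.4 ± 0.682 CPM in WT and 7.36 ± 1.48 CPM in HepKO (n = 3 each), a fall of 2.91-fold (log2FC -1.54 ± 0.16, FDR 4.69e-04). The count covers all exons of the gene and all cell types of the tissue, so it does not give the share of deleted alleles.

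**Figure D1:**
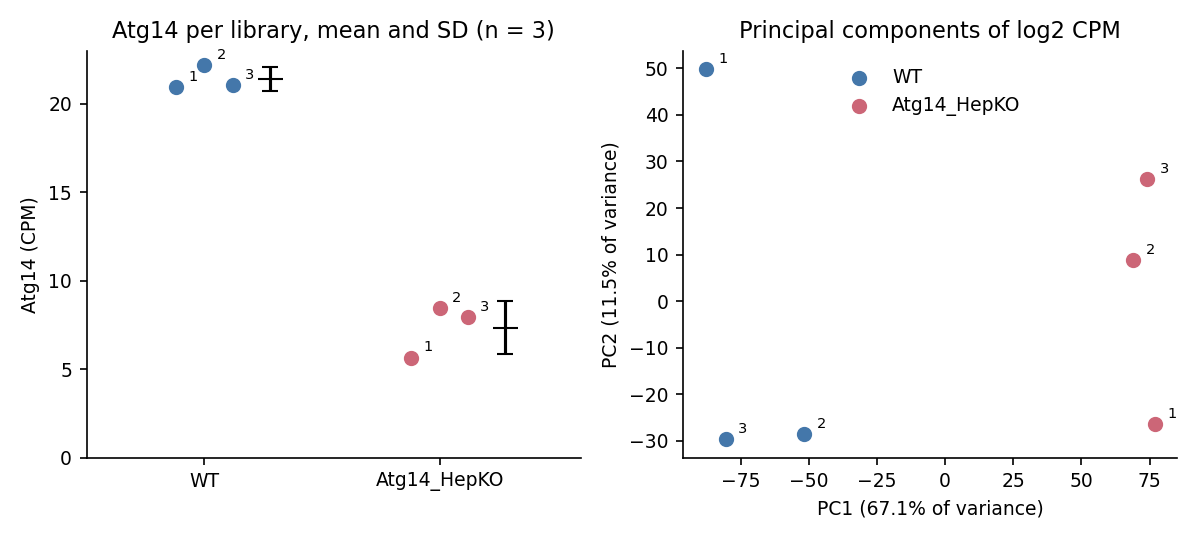
Left, Atg14 in CPM (vertical axis) for each library by group, numbered by replicate, with the group mean and SD (n = 3); the HepKO libraries lie between 5.66 and 8.45 CPM and the WT libraries between 20.9 and 22.2 CPM. Right, the libraries on the first 2 principal components of log2 CPM, where the first (67.1% of the variance) separates the groups.

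A large part of the transcriptome differed between the groups. Of 16051 genes tested, 6131 (38.2%) were called, 3125 higher and 3006 lower in HepKO. Changes of at least 2-fold were more often increases, with 2063 genes higher and 922 lower. The libraries of the groups did not overlap for 53.5% of tested genes, where chance gives 10%. The split by direction rested on the scaling: 51.0% of called genes were higher under TMM and 88.8% under library totals, with 7442 higher and 937 lower.

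The genes with the highest folds included transporters and redox enzymes. Slc1a1, a glutamate and cysteine transporter, rose from 0.0469 ± 0.0578 CPM to 77.1 ± 18.3 CPM (log2FC 10.50 ± 0.42, FDR 3.98e-05). Cbr3, a carbonyl reductase, rose to 166 ± 20.7 CPM from 0.721 ± 0.244 CPM (log2FC 7.82 ± 0.24, FDR 1.32e-05). Elovl7, a fatty acid elongase, had 0.396 ± 0.242 CPM in WT and 63.1 ± 4.78 CPM in HepKO (log2FC 7.26 ± 0.32, FDR 4.15e-05), and the transporter Abcc12 had 0.204 ± 0.129 CPM in WT and 36 ± 10.6 CPM in HepKO (log2FC 7.46 ± 0.41, FDR 6.98e-05). The protease inhibitor Spink1 (log2FC 7.42 ± 0.35, FDR 4.56e-05), the tubulin Tubb2b (log2FC 7.32 ± 0.55, FDR 1.40e-04) and the glutathione peroxidase Gpx2 (log2FC 7.06 ± 0.36, FDR 6.30e-05) also rose. Slc7a11, which imports cystine, varied widely among HepKO libraries (3.17, 29.7 and 82.9 CPM in replicates 1 to 3), and its group fold passed the test (log2FC 7.50 ± 1.36, FDR 0.00392). Apela, a peptide hormone gene, had no counts in WT and was at least 619-fold higher in HepKO, against a floor of 3 counts over the WT group (adjusted p = 0.00227). Tekt5, which encodes a tektin, had 3 WT counts and was higher by a ratio of 622 (95% counting interval 213 to 3017; adjusted p = 8.46e-05). Cyp2a4, a steroid hydroxylase with higher expression in female mouse liver, had 3609, 572 and 998 CPM in HepKO replicates 1 to 3 and 2.90 to 11.8 CPM in WT (log2FC 8.15 ± 0.99, FDR 7.78e-04). The remaining gene of the 12, Xist, was high in a single library and is described with the sex-linked genes. With limma-voom the calls of Apela (adjusted p = 0.0698) and Slc7a11 (adjusted p = 0.393) ended. Several of these folds took other values or bounds when 1 library was left out. Apela was at least 340-fold higher without HepKO replicate 3, and Tekt5, whose WT counts all lay in WT replicate 2, at least 405-fold without that library, both against the floor of 3 counts. The ratio of Slc1a1 without WT replicate 2 (1 WT count) was 5141 (95% counting interval 923 to 203073), and that of Tubb2b without WT replicate 3 (2 WT counts) was 481 (95% counting interval 133 to 3971). The log2 fold change was 9.10 for Cyp2a4 without WT replicate 2 and 6.998 without HepKO replicate 1, and for Slc7a11 it was 8.13 without WT replicate 3 and 6.27 without HepKO replicate 3.

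The lowest folds were those of Cfd and the major urinary protein genes Mup12 and Mup1, and 6 of the other 9 lowest genes were of the cytochrome P450 family. Cyp2c37 (392 ± 67.2 CPM in WT and 17.6 ± 10.9 CPM in HepKO, log2FC -4.47 ± 0.48, FDR 4.72e-04), Cyp2c54 (log2FC -4.18 ± 0.53, FDR 8.93e-04) and Cyp2c38 (log2FC -3.51 ± 0.50, FDR 0.00148) fell. Cyp4a14 (835 ± 147 CPM in WT and 47.4 ± 42.2 CPM in HepKO, log2FC -4.14 ± 0.62, FDR 0.00173) and Cyp4a10 (log2FC -3.65 ± 0.67, FDR 0.00406), fatty acid hydroxylases, fell as well. The lysophospholipid transporter Mfsd2a had 255 ± 36.8 CPM in WT and 12.1 ± 12.6 CPM in HepKO (log2FC -4.39 ± 0.73, FDR 0.00266), and the water channel Aqp4 had 30.1 ± 4.94 CPM in WT and 2.52 ± 0.573 CPM in HepKO (log2FC -3.57 ± 0.20, FDR 7.62e-05). Cyp46a1, a cholesterol hydroxylase (log2FC -3.76 ± 0.54, FDR 0.00148), and the semaphorin Sema5b (log2FC -3.80 ± 0.48, FDR 8.80e-04) were lower. Mup1 (log2FC -5.83 ± 1.20, FDR 0.00701) and Mup12 (log2FC -6.32 ± 0.77, FDR 7.77e-04) fell, with WT replicates of Mup1 at 90.4, 32.2 and 204 CPM. Cfd, the complement protease adipsin, had 12.7, 16.8 and 66.4 CPM in WT replicates and 0 to 0.102 CPM in HepKO (log2FC -9.70 ± 1.07, FDR 5.28e-04), and with limma-voom its call ended (adjusted p = 0.0638). Without HepKO replicate 1 the log2 fold change was -8.997 for Cfd, -5.21 for Mup1, -5.71 for Mfsd2a, -5.17 for Cyp4a14, -4.56 for Cyp4a10 and -4.33 for Cyp2c38. Without HepKO replicate 3 Cfd had 1 HepKO count and was lower by a ratio of 3372 (95% counting interval 605 to 133224), and the log2 fold change was -7.04 for Mup12, -7.67 for Mup1 and -4.40 for Sema5b, and without WT replicate 3 it was -8.56 for Cfd and -4.96 for Mup1.

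Changes of gene groups were followed in 44 lists fixed beforehand, of which camera called 28 among the 42 tested, 14 higher and 14 lower. No list call held with an estimated correlation between genes, where 9 lists had an unadjusted p under 0.05 and the lowest adjusted p was 0.0699. That setting also tests with the few residual degrees of freedom of 6 libraries, so a lost call does not by itself show that correlation undid it. The gluconeogenesis list had an estimated correlation of -0.0128, below the preset 0.01, yet its unadjusted camera p went from 4.42e-10 to 0.00259. fry, which does not set a list against other genes, called 31. It did not call the cholangiocyte and ductular list (adjusted p = 0.0620), which camera called. Lists that fry called and camera did not were cargo receptors (adjusted p = 0.00152), bile acid and sterol transport (0.00170), ER chaperones (0.00428) and erythrocyte markers (0.00828). The median log2FC of all tested genes was 0.01 under TMM and 0.52 under library totals, so small falls under TMM are given with their value under library totals.

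**Figure D2:**
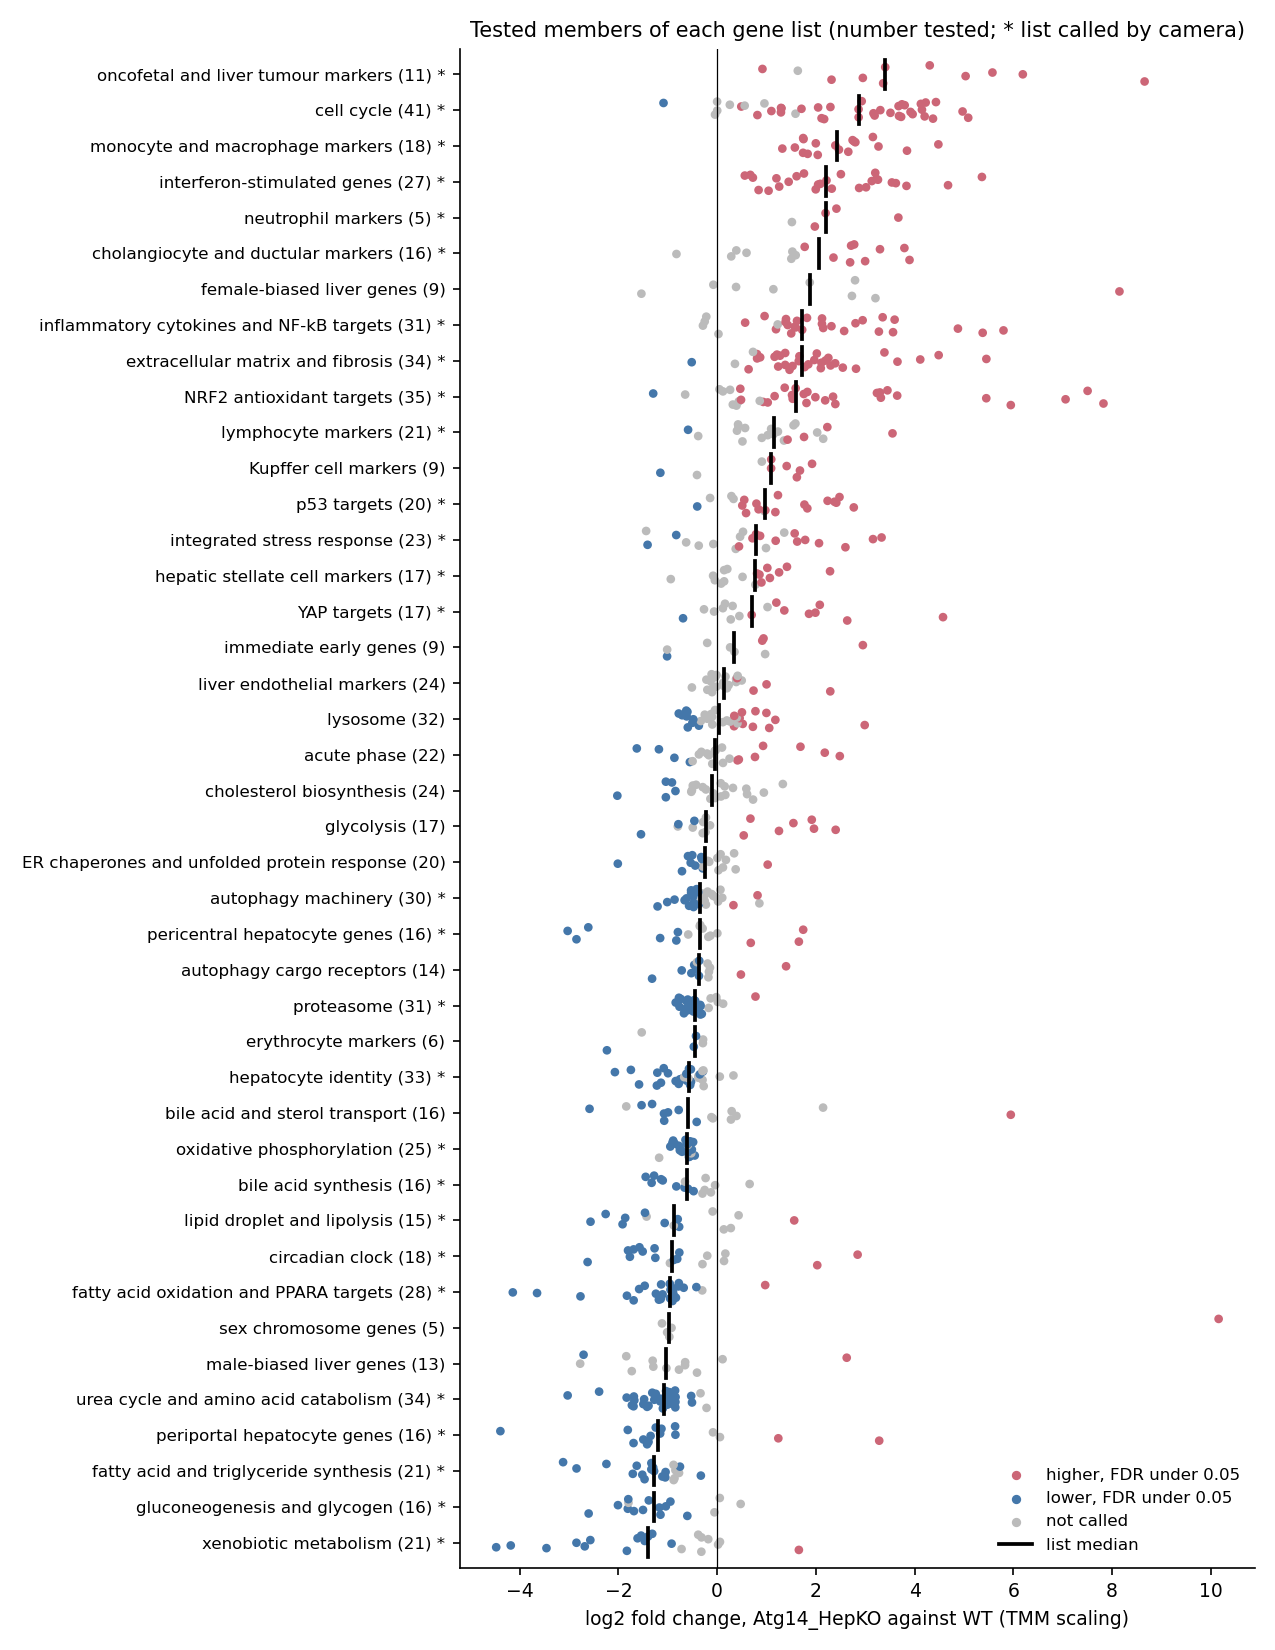
Log2 fold change of HepKO against WT under TMM scaling (horizontal axis) for each tested member of 42 gene lists (rows, ordered by median), red for genes called higher, blue for genes called lower and grey for genes not called; black bars mark list medians and stars the lists called by camera. Medians run from -1.40 for xenobiotic metabolism to 3.405 for oncofetal and liver tumour markers; under library totals the medians of autophagy machinery, cargo receptors, pericentral genes, proteasome, ER chaperones, glycolysis, cholesterol biosynthesis, acute phase and erythrocyte markers turn positive.

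The called genes of the autophagy machinery were mostly lower under TMM scaling. Of 30 tested, 15 fell and 2 rose. The autophagy machinery list had a median log2FC of -0.34 and was called (adjusted p = 0.00399), but not with an estimated correlation (adjusted p = 0.217). Atg3, the enzyme that passes LC3 to its lipid, fell (log2FC -1.01 ± 0.09, FDR 2.94e-04), as did Atg5, part of the conjugate needed for that step (log2FC -0.86 ± 0.09, FDR 5.10e-04). Map1lc3a, an LC3 isoform, rose (log2FC 0.82 ± 0.10, FDR 7.24e-04). Under library totals the sign of the list median turned, with 12 members higher, 3 lower, a median of 0.17 and no call (adjusted p = 0.218). The median of all genes was then 0.52, so the list median lay below that of all genes under both scalings. Among cargo receptors, 7 of 14 fell and 2 rose (median -0.37), which gave no list call (adjusted p = 0.0858, or 0.251 with an estimated correlation), although the list was called with no filter (adjusted p = 0.0205). Under library totals 5 were higher and 1 lower (median 0.14). Sqstm1, which encodes the receptor p62, rose from 359 ± 20.7 CPM to 946 ± 67.3 CPM (log2FC 1.40 ± 0.11, FDR 1.65e-04), while the mitophagy receptor Bnip3 (log2FC -1.32 ± 0.16, FDR 7.86e-04) and the ferritin receptor Ncoa4 (log2FC -0.72 ± 0.09, FDR 8.07e-04) fell, the latter with no call under library totals (adjusted p = 0.0816). Lysosomal genes went both ways, 11 of 32 higher and 9 lower (median 0.04; adjusted p = 0.703; 0.885 with an estimated correlation), and 21 higher with 1 lower under library totals. Cd63, a tetraspanin of late endosomes (log2FC 2.99 ± 0.33, FDR 5.28e-04), and the proton pump subunit Atp6v0e (log2FC 0.72 ± 0.09, FDR 8.85e-04) rose, and the cholesterol exporter Npc1 fell (log2FC -0.78 ± 0.10, FDR 7.94e-04). With p-values adjusted over the list alone, 2 members were higher and 18 lower in the machinery list, 2 and 8 among cargo receptors, and 13 and 9 in the lysosome list.

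Most target genes of NRF2, the transcription factor of the antioxidant response, rose. Of 35 tested, 26 rose and 1 fell. The NRF2 list had a median log2FC of 1.59 and was called (adjusted p = 4.69e-20), but not with an estimated correlation (adjusted p = 0.188). Besides Cbr3 and Gpx2, Cbr1 rose from 59.7 ± 4.17 CPM to 314 ± 40.3 CPM (log2FC 2.39 ± 0.13, FDR 6.83e-05). In the integrated stress response list 12 of 23 rose and 2 fell, led by the serine synthesis enzyme Psat1 (log2FC 3.33 ± 0.28, FDR 2.12e-04), the stress regulator Nupr1 (log2FC 3.16 ± 0.41, FDR 0.00104) and the transcription factor Atf3 (log2FC 2.60 ± 0.38, FDR 0.00166). The stress response list had a median log2FC of 0.79 and was called (adjusted p = 0.00487), but not with an estimated correlation (adjusted p = 0.26). Of 20 p53 targets, 15 rose and 1 fell, with Plk2 (log2FC 2.38 ± 0.21, FDR 2.18e-04), Mdm2 (log2FC 0.80 ± 0.10, FDR 8.79e-04) and Ccng1 (log2FC 0.84 ± 0.11, FDR 0.00107) among those that rose. The p53 list had a median log2FC of 0.97 and was called (adjusted p = 3.05e-06), but not with an estimated correlation (adjusted p = 0.151). ER chaperone and unfolded protein response genes gave no list call (adjusted p = 0.0977, or 0.252 with an estimated correlation and, called, 0.0269 with no filter), with 9 of 20 lower and 1 higher under TMM (median -0.24) and 1 lower and 10 higher under library totals (median 0.27). Herpud1, a factor of ER-associated degradation, fell (log2FC -2.01 ± 0.18, FDR 2.33e-04) and the stress sensor Ern1 rose (log2FC 1.02 ± 0.15, FDR 0.00161). Sel1l fell under TMM (log2FC -0.50 ± 0.09, FDR 0.00301) but not under library totals (log2 fold change 0.01, adjusted p = 0.950). For counts adjusted over the list alone, 28 were higher and 1 lower for NRF2, 12 and 3 for the stress response, 16 and 1 for p53, and 1 and 10 for the ER list.

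Subunits of the respiratory chain and of the proteasome were lower under TMM. Of 25 oxidative phosphorylation genes, 22 fell and 0 rose, including Ndufs1 (log2FC -0.95 ± 0.10, FDR 4.68e-04) and Sdha (log2FC -0.86 ± 0.10, FDR 7.86e-04). The oxidative phosphorylation list had a median log2FC of -0.61 and was called (adjusted p = 9.13e-08), but not with an estimated correlation (adjusted p = 0.3). Of 31 proteasome subunits, 25 fell and 1 rose, including Psmd1 (log2FC -0.84 ± 0.09, FDR 5.21e-04), Psmb7 (log2FC -0.76 ± 0.09, FDR 7.56e-04) and Psmd3 (log2FC -0.73 ± 0.09, FDR 9.09e-04). The proteasome list had a median log2FC of -0.45 and was called (adjusted p = 1.91e-05), but not with an estimated correlation (adjusted p = 0.26). Under library totals 5 oxidative phosphorylation genes were lower and 0 higher (median -0.10), and the proteasome turned, with 2 lower and 6 higher (median 0.07). Both lists stayed called lower than other genes under library totals (adjusted p = 9.43e-06 and 0.0266), which raise the median of all genes to 0.52. Psmd3 was then not called (adjusted p = 0.0769). Adjusted over the list alone, 0 were higher and 24 lower in the first list, and 1 and 25 in the second.

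Many genes that mark hepatocyte function fell. Of 33 hepatocyte identity genes, 22 fell and 0 rose. Under library totals 8 were lower and 2 higher (median -0.06), and the list stayed called lower than other genes (adjusted p = 1.50e-06). The hepatocyte identity list had a median log2FC of -0.57 and was called (adjusted p = 9.53e-08), but not with an estimated correlation (adjusted p = 0.188). The nuclear receptors Ppara (log2FC -1.75 ± 0.15, FDR 1.94e-04) and Nr1h4, the bile acid receptor (log2FC -0.995 ± 0.11, FDR 4.59e-04), fell, as did the apolipoprotein gene Apoa2 (4476 ± 475 CPM in WT and 1496 ± 171 CPM in HepKO, log2FC -1.58 ± 0.15, FDR 3.12e-04). Of 16 bile acid synthesis genes, 9 fell and 0 rose. Under library totals 3 were lower and 2 higher (median -0.10), and the list stayed called lower than other genes (adjusted p = 0.00208). The bile acid synthesis list had a median log2FC of -0.62 and was called (adjusted p = 0.00214), but not with an estimated correlation (adjusted p = 0.265). Slc27a5 (log2FC -1.28 ± 0.12, FDR 2.86e-04) and Hsd17b4 (log2FC -1.14 ± 0.14, FDR 8.45e-04) fell, and so did Baat (log2FC -0.66 ± 0.11, FDR 0.00315), without a call under library totals (adjusted p = 0.263). Transport genes for bile acids and sterols gave no list call (adjusted p = 0.119, or 0.26 with an estimated correlation and, called, 0.0226 without HepKO replicate 1 and 0.0349 with no filter, over a range of 0.0226 to 0.232). Of 16, 8 fell and 1 rose (median -0.60), with 3 lower and 5 higher under library totals (median -0.09). The uptake transporters Slc10a1 (log2FC -2.58 ± 0.26, FDR 3.99e-04) and Slco1b2 (log2FC -1.32 ± 0.16, FDR 7.25e-04) fell, while the efflux pump Abcc4 rose from 2.90 ± 1.66 CPM to 180 ± 27.7 CPM (log2FC 5.95 ± 0.40, FDR 1.19e-04). Of 21 xenobiotic metabolism genes, 13 fell and 1 rose, led by Cyp3a11 (2885 ± 335 CPM in WT and 486 ± 72.7 CPM in HepKO, log2FC -2.57 ± 0.16, FDR 9.83e-05), Cyp2j5 (log2FC -1.47 ± 0.12, FDR 1.65e-04) and Cyp2c50 (log2FC -2.68 ± 0.22, FDR 1.72e-04). Under library totals 12 were lower and 1 higher (median -0.89). The xenobiotic list had a median log2FC of -1.40 and was called (adjusted p = 7.18e-09), but not with an estimated correlation (adjusted p = 0.238). With p-values adjusted over the list alone, 23 were lower for identity, 9 for bile acid synthesis, 8 for transport and 13 for xenobiotic metabolism, and 0, 0, 2 and 1 were higher.

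Genes of lipid metabolism fell in the making and the burning of fatty acids alike. Of 21 fatty acid and triglyceride synthesis genes, 16 fell and 0 rose, with Lpin1 (375 ± 84.6 CPM in WT and 52.1 ± 8.49 CPM in HepKO, log2FC -2.85 ± 0.20, FDR 1.31e-04), Thrsp (781 ± 79 CPM in WT and 89.8 ± 32.1 CPM in HepKO, log2FC -3.12 ± 0.25, FDR 1.64e-04) and the triglyceride-forming enzyme Dgat2 (log2FC -1.52 ± 0.12, FDR 1.51e-04). The fatty acid synthesis list had a median log2FC of -1.28 and was called (adjusted p = 1.79e-11), but not with an estimated correlation (adjusted p = 0.151). Of 28 fatty acid oxidation and PPARA target genes, 26 fell and 1 rose, including the dehydrogenase Acadl (log2FC -1.14 ± 0.10, FDR 2.60e-04) and the acylcarnitine transferase Cpt2 (log2FC -1.24 ± 0.12, FDR 3.51e-04). The fatty acid oxidation list had a median log2FC of -0.95 and was called (adjusted p = 1.07e-13), but not with an estimated correlation (adjusted p = 0.217). Of 15 lipid droplet and lipolysis genes, 8 fell and 1 rose, with Plin5 (log2FC -1.46 ± 0.18, FDR 8.32e-04), Fitm2 (log2FC -1.06 ± 0.14, FDR 0.00103) and Cideb (log2FC -0.77 ± 0.11, FDR 0.00161; under library totals adjusted p = 0.0851) lower. Under library totals 12 and 20 genes of the first 2 lists were lower and 0 and 1 higher (medians -0.77 and -0.44), and in the lipid droplet list 6 were lower and 5 higher (median -0.37). The lipid droplet list had a median log2FC of -0.88 and was called (adjusted p = 0.00283), but not with an estimated correlation (adjusted p = 0.352). Cholesterol biosynthesis gave no list call (adjusted p = 0.231, or 0.813 with an estimated correlation), and 5 of 24 fell and 0 rose (median -0.11). Under library totals 2 were lower and 5 higher (median 0.40). Ebp (log2FC -1.04 ± 0.12, FDR 6.17e-04) and Tm7sf2 (log2FC -1.04 ± 0.17, FDR 0.00252) were lower. Without WT replicate 3 the cholesterol list was called (adjusted p = 0.00785, over a range of 0.00785 to 0.585). For counts adjusted over the list alone, 17, 26, 8 and 4 members were lower in these lists, in the order given, and 0, 1, 1 and 0 higher.

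Genes of gluconeogenesis, glycogen and amino acid metabolism fell as well, while those of glycolysis went both ways. Of 16 gluconeogenesis and glycogen genes, 12 fell and 0 rose, including the glucose-phosphate transporter Slc37a4 (log2FC -1.80 ± 0.09, FDR 6.17e-05), the liver glycogen synthase Gys2 (log2FC -1.50 ± 0.11, FDR 1.40e-04) and the glucose transporter Slc2a2 (log2FC -1.38 ± 0.11, FDR 1.65e-04). Under library totals 10 were lower and 3 higher (median -0.77). The gluconeogenesis list had a median log2FC of -1.28 and was called (adjusted p = 1.69e-09), but not with an estimated correlation (adjusted p = 0.0699). Of 34 urea cycle and amino acid catabolism genes, 32 fell and 0 rose. Under library totals 25 were lower and 0 higher (median -0.55). The amino acid list had a median log2FC of -1.07 and was called (adjusted p = 2.33e-19), but not with an estimated correlation (adjusted p = 0.151). Mat1a, which makes S-adenosylmethionine, fell (3873 ± 69.8 CPM in WT and 1204 ± 83.2 CPM in HepKO, log2FC -1.69 ± 0.12, FDR 1.35e-04), as did Haao (log2FC -1.48 ± 0.11, FDR 1.35e-04) and the mitochondrial carrier Slc25a13 (log2FC -1.31 ± 0.10, FDR 1.59e-04). Glycolysis genes gave no list call (adjusted p = 0.76, or 0.884 with an estimated correlation), with 7 of 17 higher and 3 lower, a median of -0.23 and a mean of 0.30, and 8 higher and 1 lower under library totals (median 0.28). Pkm (log2FC 1.92 ± 0.27, FDR 0.00142) and Hk3 (log2FC 1.96 ± 0.33, FDR 0.00288) rose. Adjusted over the list alone, 13, 32 and 5 were lower and 0, 0 and 7 higher.

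The called zonation and clock genes were mostly lower. Of 16 periportal genes, 12 fell and 2 rose, with Ass1 (log2FC -1.39 ± 0.13, FDR 2.79e-04) and Asl (log2FC -1.69 ± 0.15, FDR 2.54e-04) of the urea cycle lower and the cadherin gene Cdh1 higher (log2FC 3.28 ± 0.29, FDR 2.36e-04). Under library totals 9 were lower and 2 higher (median -0.69). The periportal list had a median log2FC of -1.20 and was called (adjusted p = 7.46e-05), but not with an estimated correlation (adjusted p = 0.193). Of 16 pericentral genes, 6 fell and 3 rose, with Cyp2e1 (12896 ± 2291 CPM in WT and 1790 ± 522 CPM in HepKO, log2FC -2.85 ± 0.26, FDR 2.79e-04), Oat (log2FC -3.03 ± 0.26, FDR 2.13e-04) and Slc1a2 (log2FC -2.61 ± 0.29, FDR 5.25e-04) lower. The pericentral list had a median log2FC of -0.35 and was called (adjusted p = 0.0089), but not with an estimated correlation (adjusted p = 0.194). Under library totals 4 pericentral genes were lower, 4 higher, and the median turned to 0.16, while the list stayed called lower than other genes (adjusted p = 0.00391). Of 18 circadian clock genes, 11 fell and 2 rose, and the output factors Hlf (log2FC -1.77 ± 0.11, FDR 8.68e-05), Tef (log2FC -1.57 ± 0.11, FDR 1.19e-04) and Dbp (log2FC -1.25 ± 0.12, FDR 2.79e-04) fell. Under library totals 8 were lower and 3 higher (median -0.41). The clock list had a median log2FC of -0.92 and was called (adjusted p = 1.56e-06), but not with an estimated correlation (adjusted p = 0.151). With p-values adjusted over the list alone, 12, 7 and 11 were lower and 2, 3 and 2 higher.

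Most interferon, inflammatory and macrophage genes rose. Of 27 interferon-stimulated genes, 27 rose: the antiviral gene Rsad2 went from 12.1 ± 0.595 CPM to 499 ± 152 CPM (log2FC 5.36 ± 0.24, FDR 4.15e-05), and Oas1a (log2FC 3.13 ± 0.14, FDR 4.15e-05) and Usp18 (log2FC 2.51 ± 0.16, FDR 9.83e-05) rose with it. The interferon list had a median log2FC of 2.21 and was called (adjusted p = 9.05e-33), but not with an estimated correlation (adjusted p = 0.151). Of 31 inflammatory and NF-kB target genes, 26 rose and 0 fell, including the receptor Tnfrsf12a (log2FC 3.35 ± 0.15, FDR 4.15e-05), the chemokine Cxcl16 (log2FC 2.15 ± 0.13, FDR 8.97e-05) and Csf1, the growth factor of macrophages (log2FC 1.72 ± 0.11, FDR 8.97e-05). The inflammatory list had a median log2FC of 1.72 and was called (adjusted p = 1.23e-14), but not with an estimated correlation (adjusted p = 0.151). All 18 monocyte and macrophage markers tested rose, among them Cd14 (log2FC 3.85 ± 0.33, FDR 2.12e-04), Cx3cr1 (log2FC 3.27 ± 0.32, FDR 3.41e-04) and Mpeg1 (138 ± 36.6 CPM in WT and 463 ± 50.4 CPM in HepKO, log2FC 1.74 ± 0.19, FDR 5.29e-04). The monocyte and macrophage list had a median log2FC of 2.43 and was called (adjusted p = 1.16e-13), but not with an estimated correlation (adjusted p = 0.188). Of 9 Kupffer cell markers 6 rose and 1 fell (median 1.10), without a list call (adjusted p = 0.0596, or 0.536 with an estimated correlation). Of these, Adgre1 (log2FC 1.61 ± 0.29, FDR 0.0039), Cd5l (log2FC 1.68 ± 0.32, FDR 0.00499) and Folr2 (log2FC 1.41 ± 0.31, FDR 0.00882) rose. The Kupffer list was called without WT replicate 2 (adjusted p = 0.0037), without HepKO replicate 2 (adjusted p = 0.0042) and with no filter (adjusted p = 0.00627), over a range of 0.0037 to 0.237. Acute phase genes gave no list call (adjusted p = 0.865, or 0.896 with an estimated correlation, median -0.04, mean 0.16), with 7 of 22 higher and 4 lower, against 10 higher and 1 lower under library totals (median 0.46). Lcn2 rose (log2FC 2.48 ± 0.39, FDR 0.00223), and Itih4 (log2FC -0.87 ± 0.14, FDR 0.00215) and Crp (log2FC -0.55 ± 0.10, FDR 0.00445) fell, without a call under library totals (adjusted p = 0.0583 and 0.748). For counts adjusted over the list alone, 27, 27, 18, 6 and 7 were higher and 0, 0, 0, 1 and 4 lower.

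Most markers of lymphocytes and neutrophils were low in both groups. Of 21 lymphocyte markers, 4 rose and 1 fell, including Cd8a (0.17 ± 0.109 CPM in WT and 2.04 ± 0.437 CPM in HepKO; log2FC 3.55 ± 0.52, FDR 0.00161; log2 fold change 4.22 without WT replicate 3), Lck (log2FC 2.23 ± 0.44, FDR 0.00557) and Cd3g (log2FC 1.76 ± 0.40, FDR 0.0106). The 4 lymphocyte markers called higher were no larger a share than among all tested genes (3125 of 16051). The lymphocyte list had a median log2FC of 1.14 and was called (adjusted p = 0.0469), but not with an estimated correlation (adjusted p = 0.525). That list call ended under library totals (adjusted p = 0.620), RLE factors (adjusted p = 0.0518), the CPM filter (adjusted p = 0.0916) and the replicate block (adjusted p = 0.0566). It also ended without WT replicate 1 (adjusted p = 0.0809), WT replicate 3 (adjusted p = 0.0844) or HepKO replicate 1 (adjusted p = 0.196), over a range of 0.00773 to 0.62. Of 5 neutrophil markers tested, 4 rose, with Csf3r (log2FC 1.98 ± 0.46, FDR 0.0116; log2 fold change 2.67 without WT replicate 2), S100a9 (log2FC 2.42 ± 0.59, FDR 0.0145) and S100a8 (log2FC 2.20 ± 0.56, FDR 0.0174). The rest of the 14 listed neutrophil markers, among them Ly6g, Mpo, Elane and Cxcr2, did not pass the filter and had at most 45 counts in a library. The neutrophil list had a median log2FC of 2.20 and was called (adjusted p = 0.0424), but not with an estimated correlation (adjusted p = 0.418). The neutrophil call ended under library totals (adjusted p = 0.247), the CPM filter (adjusted p = 0.108), the replicate block (adjusted p = 0.0691) and without HepKO replicate 1 (adjusted p = 0.0848), over a range of 0.00173 to 0.247. S100a9 was not called without WT replicate 3 (adjusted p = 0.0541), and neither S100a9 (adjusted p = 0.0508) nor S100a8 (adjusted p = 0.0643) without HepKO replicate 3. With the replicate block neither was called (adjusted p = 0.0606 for S100a9 and 0.0680 for S100a8), nor was S100a9 with limma-voom (adjusted p = 0.0851). Adjusted over the list alone, 3 lymphocyte and 4 neutrophil markers were higher and 0 and 0 lower.

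Most matrix genes rose. Of the cell markers, 8 of 17 stellate, 9 of 16 ductular and 4 of 24 endothelial ones were called higher. Among all tested genes 3125 of 16051 were called higher, and the endothelial share was not above that. Of 34 extracellular matrix and fibrosis genes, 31 rose and 1 fell, with Sparc (45.2 ± 5.4 CPM in WT and 143 ± 19.8 CPM in HepKO, log2FC 1.67 ± 0.14, FDR 1.89e-04), the collagen crosslinker Loxl2 (log2FC 2.19 ± 0.19, FDR 2.13e-04) and Lum (log2FC 1.97 ± 0.19, FDR 3.26e-04). The matrix list had a median log2FC of 1.72 and was called (adjusted p = 9.79e-15), but not with an estimated correlation (adjusted p = 0.188). Of 17 stellate cell markers, 8 rose and 0 fell, with Vim (log2FC 1.41 ± 0.20, FDR 0.00131) and Cygb (log2FC 0.90 ± 0.15, FDR 0.00311). The stellate list had a median log2FC of 0.78 and was called (adjusted p = 0.0089), but not with an estimated correlation (adjusted p = 0.338). Of 16 cholangiocyte and ductular markers, 9 rose and 0 fell, with Sox4 (log2FC 3.79 ± 0.32, FDR 2.12e-04), Bicc1 (log2FC 2.69 ± 0.31, FDR 6.26e-04) and Spp1 (log2FC 2.71 ± 0.47, FDR 0.00335; 1.95 without HepKO replicate 2). Under library totals the ductular list was not called (adjusted p = 0.0827, over a range of 4.27e-06 to 0.0827). The ductular list had a median log2FC of 2.06 and was called (adjusted p = 0.00181), but not with an estimated correlation (adjusted p = 0.435). Of 24 liver endothelial markers, 4 rose and 0 fell (median 0.15; adjusted p = 0.417; 0.863 with an estimated correlation), against 14 higher under library totals. These were led by Flt4 (log2FC 1.001 ± 0.22, FDR 0.00837), Cd34 (log2FC 2.29 ± 0.49, FDR 0.00842) and Cdh5 (log2FC 0.74 ± 0.18, FDR 0.0143), the last not called without WT replicate 1 (adjusted p = 0.0527) or WT replicate 3 (adjusted p = 0.0523). With p-values adjusted over the list alone, 32, 8, 9 and 3 were higher and 1, 1, 0 and 0 lower.

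Most cell cycle genes and most of the tested oncofetal and liver tumour markers rose. Of 41 cell cycle genes, 33 rose and 1 fell, including Mki67 (2.22 ± 0.995 CPM in WT and 28.6 ± 10.4 CPM in HepKO, log2FC 3.67 ± 0.39, FDR 4.68e-04), the mitotic cyclin Ccnb1 (log2FC 4.20 ± 0.44, FDR 4.40e-04) and the spindle factor Tpx2 (log2FC 4.43 ± 0.36, FDR 1.80e-04). The cell cycle list had a median log2FC of 2.87 and was called (adjusted p = 5.36e-14), but not with an estimated correlation (adjusted p = 0.238). Of 11 oncofetal and liver tumour markers tested, out of 14 listed, 10 rose and 0 fell. Igf2, Igf2bp3 and Dlk1 did not pass the filter, with at most 19 counts in a library. The oncofetal list had a median log2FC of 3.405 and was called (adjusted p = 4.17e-10), but not with an estimated correlation (adjusted p = 0.0699). Afp, the fetal serum protein, had 1.64 ± 0.144 CPM in WT and 16.9 ± 4.08 CPM in HepKO (log2FC 3.36 ± 0.22, FDR 1.11e-04), and the cell-surface proteoglycan Gpc3 rose (log2FC 5.03 ± 0.41, FDR 1.80e-04). Akr1c18 had 2 WT counts and was higher by a ratio of 453 (95% counting interval 125 to 3742; adjusted p = 3.99e-04). Both WT counts lay in WT replicate 3, and without it Akr1c18 was at least 201-fold higher against the floor of 3 counts. Of 17 YAP targets, 8 rose and 1 fell, with Ajuba (log2FC 2.63 ± 0.14, FDR 6.98e-05), Ccn1 (log2FC 1.99 ± 0.19, FDR 3.07e-04) and Crim1 (log2FC 1.36 ± 0.19, FDR 0.00125). The YAP list had a median log2FC of 0.70 and was called (adjusted p = 5.42e-04), but not with an estimated correlation (adjusted p = 0.188). Immediate early genes gave no list call (adjusted p = 0.417, or 0.775 with an estimated correlation, median 0.35), with 3 of 9 higher and 1 lower. Ier3 rose (log2FC 2.95 ± 0.41, FDR 0.00128), while the calls of Junb (log2FC 0.91 ± 0.26, FDR 0.0279) and Dusp1 (log2FC -1.01 ± 0.32, FDR 0.0376) ended without single libraries. Junb had adjusted p values of 0.0680, 0.0731 and 0.0924 without WT replicate 2, WT replicate 3 and HepKO replicate 3. Dusp1 had 0.0884, 0.115, 0.107 and 0.115 without WT replicates 1 and 2 and HepKO replicates 2 and 3, and 0.215 under library totals. For counts adjusted over the list alone, 35, 11, 9 and 3 were higher and 1, 0, 1 and 1 lower.

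HepKO replicate 1 differed from the other 5 libraries in its sex-linked genes. Xist, the RNA of the inactive X chromosome, had 523 CPM in that library and 0.0676 to 0.490 CPM elsewhere, so its group fold (log2FC 10.16 ± 3.12, FDR 0.0347) rested on this library and was 1.53 without it (adjusted p = 0.153). Its call also ended with limma-voom (adjusted p = 0.628), the replicate block (adjusted p = 0.0593) and without any 1 of the WT libraries (adjusted p = 0.0926 to 0.105). The Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y together had 0.293 CPM (17 counts) in HepKO replicate 1 and 156 to 230 CPM in the other libraries. In the sex chromosome list 1 of 5 was higher and 0 lower (median -0.97, mean 1.23; adjusted p = 0.492; 0.711 with an estimated correlation). Uty was not called (log2FC -1.12, FDR 0.435), but was called lower without HepKO replicate 1 (log2 fold change -0.53, adjusted p = 0.0199). That fall is under TMM, and library totals were not run without this library. With all libraries they raised the median of all genes from 0.01 to 0.52, so a fall of this size in Uty may rest on the scaling. Female-biased liver genes had a median of 1.88 with this library and -2.28 without it, and gave no list call (adjusted p = 0.585, or 0.884 with an estimated correlation, 1 of 9 higher, 0 lower). Only 9 of the 15 listed genes were tested. Sult2a2, Cyp3a41a, Sult2a1 and Cyp3a16 reached 1306, 501, 465 and 293 counts in a library, but were expressed in too few libraries to pass the filter. The list result therefore leaves out genes that were high in only some libraries. The called member was Cyp2a4, while Cux2 (log2FC 2.73 ± 1.10, FDR 0.0852) and A1bg (log2FC 3.21 ± 1.602, FDR 0.152) were highest in HepKO replicate 1, at 6.56 and 5.60 CPM. Cux2 was called with DESeq2, under library totals, with no filter and without HepKO replicate 2 (adjusted p = 0.00215 to 0.0413), and A1bg with no filter (adjusted p = 0.00823) and without HepKO replicate 2 (adjusted p = 0.0494). Male-biased genes had a median of -1.03 (adjusted p = 0.0977, or 0.711 with an estimated correlation, 1 of 13 higher, 1 lower). The male-biased list was called lower under library totals (adjusted p = 0.00114) and with no filter (adjusted p = 0.0108). It was also called without WT replicate 2 (adjusted p = 0.0207), HepKO replicate 2 (adjusted p = 0.0158) or HepKO replicate 3 (adjusted p = 0.0316), over a range of 0.00114 to 0.196. Susd4 fell (log2FC -2.71 ± 0.55, FDR 0.00643; -3.45 without HepKO replicate 2) and Elovl3 was at 0.0690, 31.3 and 18.0 CPM in HepKO replicates 1 to 3 (log2FC -2.77 ± 1.15, FDR 0.0935), and was called lower with limma-voom (adjusted p = 0.0272), with no filter (adjusted p = 1.92e-04) and without HepKO replicate 1 (adjusted p = 0.00225). Selenbp2 rose (log2FC 2.62 ± 0.81, FDR 0.035), with values of 61.5, 343 and 405 CPM in HepKO. Its log2FC was 3.66 without WT replicate 3, and it was not called without WT replicates 1 or 2 or HepKO replicates 2 or 3 (adjusted p = 0.105, 0.0802, 0.0903 and 0.0992). Without HepKO replicate 1, 5587 genes were called, 2691 higher and 2896 lower, and 83.2% of the 6131 calls were kept. Adjusted over the list alone, 0, 1 and 0 were higher and 0, 0 and 1 lower.

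**Figure D3:**
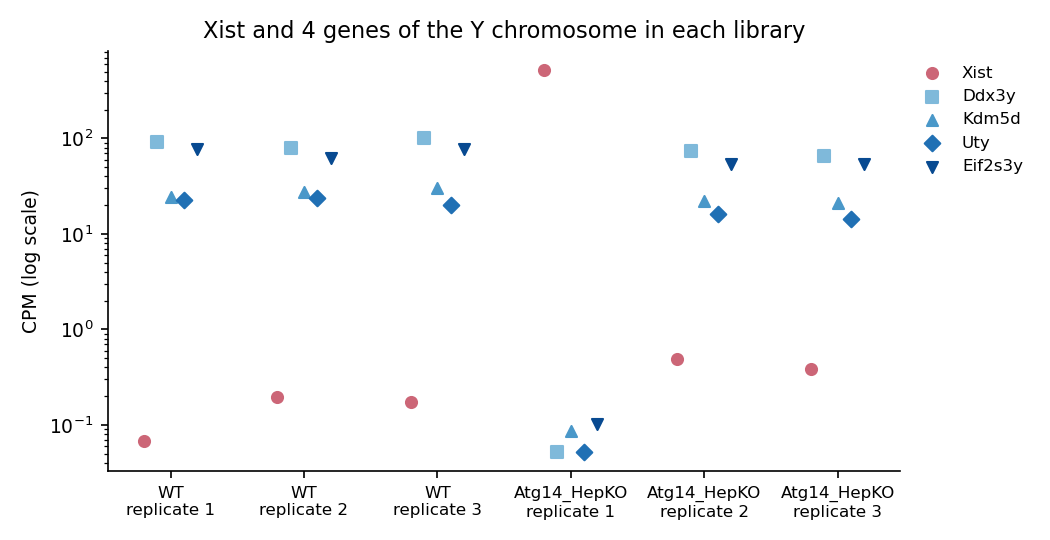
Xist and the Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y in CPM (vertical axis, log scale) for each of the 6 libraries (horizontal axis). HepKO replicate 1 had 523 CPM of Xist and 0.0517 to 0.103 CPM of each Y-linked gene, while the other libraries had Xist at 0.490 CPM or less.

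Markers of blood, fat and pancreas were followed as signs of other tissue. Of 6 erythrocyte markers, 3 fell and 0 rose (median -0.45, and 0.06 under library totals), without a list call (adjusted p = 0.0731, or 0.3 with an estimated correlation). Alas2, of haem synthesis, fell (log2FC -2.23 ± 0.43, FDR 0.00533). Hba-a1 (log2FC -0.47 ± 0.15, FDR 0.0357) and Hbb-bt (log2FC -0.43 ± 0.13, FDR 0.0315) were called lower under TMM, but stood at 0.04 and 0.08 under library totals, and Hbb-bt lost its call without any 1 of the 6 libraries (adjusted p = 0.0570 to 0.0988), with no filter (adjusted p = 0.0781) and with the replicate block (adjusted p = 0.0659). Hba-a1 lost it without WT replicates 2 or 3 or HepKO replicates 2 or 3 (adjusted p = 0.0896 to 0.158), and with the replicate block (adjusted p = 0.0797). The erythrocyte list was called without WT replicate 1 (adjusted p = 0.0430), HepKO replicate 1 (adjusted p = 0.0460) and HepKO replicate 3 (adjusted p = 0.0480), with no filter (adjusted p = 0.0118) and with the replicate block (adjusted p = 0.0289), over a range of 0.0118 to 0.133. Of 6 adipocyte markers 2 were tested, too few for a list test: Cfd was lower, and Fabp4 was higher (log2FC 0.90 ± 0.27, FDR 0.0329), a call that ended without any of WT replicates 1 to 3 or HepKO replicates 2 and 3 (adjusted p = 0.0600 to 0.112), with limma-voom (adjusted p = 0.0864) and with the replicate block (adjusted p = 0.0809). None of 8 pancreatic acinar markers passed the filter. With p-values adjusted over the list alone, 0 erythrocyte markers were higher and 4 lower, and 1 adipocyte marker was higher and 1 lower.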

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

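Counts of called genes stayed within 1.5 times of the reported ones except under library totals and the stricter thresholds. Leaving out each library gave 4392 to 5587 genes, and 69.8% to 83.2% of the 6131 calls were kept. DESeq2 kept 98.6% of them, limma-voom 96.3% and RLE factors 98.0%. Library totals called 7442 genes higher and 937 lower and kept 66.3%. An FDR under 0.01 gave 3444 genes (1751 higher, 1693 lower), and an absolute log2FC of at least 1 gave 2985 (2063 higher, 922 lower), which follows from the stricter thresholds. The log2FC of Atg14 kept its direction and call in all 14 other settings, from -1.03 under library totals to -1.66 without HepKO replicate 2. Under library totals, Hba-a1 (0.0371), Hbb-bt (0.0841) and Sel1l (0.0071) changed sign, as did the medians of 9 lists, of which autophagy machinery (0.17), proteasome (0.066) and pericentral genes (0.16) were called under TMM. The scaling shifts all genes by construction, and the proteasome (adjusted p = 0.0266) and pericentral lists (adjusted p = 0.00391) stayed called lower than other genes. With an estimated correlation camera called 0 lists, against 28 with the preset one, and 9 had an unadjusted p under 0.05. That setting also has fewer degrees of freedom, so the lost calls were not put down to correlation alone. Over all settings, named genes stayed on the same side of the threshold, without a turn of a called fold, in 1999 cases, lost the call in 56, gained it in 10 and reversed in 3. Lists did so in 522 cases, some of them uncalled lists whose median changed sign, lost the call in 41, gained it in 22 and reversed in 3. The replicate block called 5071 genes (2569 higher, 2502 lower). Same-numbered libraries did not deviate together (correlations -0.12, -0.07 and 0.00), and no library correlated best with its own number, so the numbers were not taken to pair the samples. Of genes changed 2-fold in simulated counts, 40.3% were recovered, and 56.5% at 5 CPM or more. Few genes were changed there, so these rates do not give the power of the real comparison. Genes not called were not read as unchanged.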

Other observations

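Some gene families outside the fixed lists held several called genes. Symbol stems shared by at least 6 tested genes were tested with camera after the list results were seen, and 48 of 339 stems were called. None was called with an estimated correlation, where 15 had an unadjusted p under 0.05. With 6 libraries that setting has few degrees of freedom, so a lost call is not evidence against a stem. Many stems share the adjusted p of 0.825 given below, a tie of the adjustment over 339 stems that does not rank them. All 16 Pex genes, which build peroxisomes, fell (median log2FC -0.66, adjusted p = 1.30e-04, or 0.825 with an estimated correlation), and the median was -0.14 under library totals. Pex5 had 155 ± 4.72 CPM in WT and 94.1 ± 3.69 CPM in HepKO. Of 48 Mrpl genes of the mitochondrial ribosome 21 fell (median -0.31, adjusted p = 0.00662, or 0.871 with an estimated correlation), but the median turned to 0.20 under library totals. Of 49 Rpl genes, mostly of the cytosolic ribosome, 20 rose (median 0.32, adjusted p = 0.0238, or 0.931 with an estimated correlation), a call that ended without HepKO replicate 1 (adjusted p = 0.0709).

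Of 6 beta tubulin genes (Tubb) 5 rose (median 2.31, adjusted p = 5.40e-08, or 0.825 with an estimated correlation), Tubb5 with 36.6 ± 5.95 CPM in WT and 143 ± 10.7 CPM in HepKO. Of 11 Serpinb genes, intracellular protease inhibitors, 9 rose (median 4.47, adjusted p = 1.04e-04, or 0.825 with an estimated correlation), and Serpinb6a had 12.6 ± 4.11 CPM in WT and 152 ± 17.4 CPM in HepKO. Genes of the mouse major histocompatibility complex (H2) rose in 17 of 26 cases and fell in 2 (median 1.33, adjusted p = 2.18e-04, or 0.825 with an estimated correlation). H2-Q1 had 15 ± 5.98 CPM in WT and 89.7 ± 7.59 CPM in HepKO, while H2-Q10, which encodes a class I protein secreted by liver, had 1866 ± 85.9 CPM in WT and 1020 ± 62.6 CPM in HepKO. Of 17 Mup genes 6 fell (median -2.90, adjusted p = 0.00568, or 0.873 with an estimated correlation). The genes named here were chosen after their values were seen, and reads shared within these families make their members uncertain.

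For the 3 patterns below, the tests of a mixed library, of an exchange with a WT library, of a hepatocyte share and of the scaling of respiratory chain and proteasome genes were chosen after the values they measure had been seen. The first pattern is that HepKO replicate 1 had Xist at 523 CPM and almost no Y-linked reads. RNA of animals of both sexes mixed in this library would leave a share of Y-linked reads. The sum of the 4 Y genes was 0.182% of the mean of the other HepKO libraries, which argues against such a mix. That this library sets the calls of the whole comparison is also argued against: 83.2% of the calls were kept without it, against 76.0% without HepKO replicate 2 and 74.1% without HepKO replicate 3. An exchange with a WT library would need Atg14 at the WT level here and a WT library at the HepKO level. Atg14 in HepKO replicate 1 was 27.0% of the lowest WT library, and no WT library fell to the HepKO range, which argues against it. A female animal of the HepKO group, or a sample from outside these 6 under a wrong label, stays open. A sex difference within the HepKO group may move the size of changes in genes such as Cyp2a4 and the Mup family. Without this library Cyp2a4 stayed higher (log2 fold change 6.998, edgeR adjusted p = 4.46e-04). The Mup stem stayed lower (median -2.34, camera adjusted p = 0.00500 with the preset correlation). These values argue against this library as the only source of both changes.

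The second pattern is the rise of interferon, macrophage, matrix and cell cycle genes. A lower share of hepatocyte RNA, raising markers of every other cell type alike, would move endothelial markers as much as macrophage markers. The macrophage median exceeded the endothelial one by 2.28 (95% bootstrap interval 1.64 to 2.76). This bears on the macrophage list only, since the interferon, matrix and cell cycle lists were not compared in this way. Members of the macrophage and endothelial lists varied together (estimated correlation 0.499 and 0.447), so the interval was not read as spread between samples. Under 3 other scalings the lowest median of the 4 lists of this pattern was 1.72. Those scalings put the median of all genes at 0.02 (RLE), 0.52 (library totals) and 0.01 (20 most abundant genes left out), against 0.01 under TMM. None of them could have brought the list medians to 0, so the test could not decide on scaling. HepKO replicate 1 alone does not account for the rise, with a lowest median of 1.75 without that library. Bulk counts do not tell which cells of the liver carried the rise. An effect of the Atg14 deletion, on hepatocytes or on other cells, is a hypothesis that was not tested and stays open. Differences in age or housing, which the labels do not give, stay open as well. The splits of the 6 libraries are too few for a share under 0.05: 1 of 10 splits, the real one, gave as many genes, with 6131 called against at most 0 in the other 9, where edgeR found 106 to 393 genes at an unadjusted p under 0.05. Each of the other 9 splits mixed WT and HepKO libraries, which puts the group difference into the spread within a side. Their counts therefore do not show what samples without a group difference would give.

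The third pattern is the fall of oxidative phosphorylation and proteasome genes. Whether these genes fell or other genes rose cannot be told apart by the choice of scaling: library totals shift all genes, and the higher of the 2 medians was then 0.066 where that of all genes was 0.52. Against other genes both lists stayed called lower (adjusted p = 9.43e-06 and 0.0266), with medians 0.620 and 0.454 below that of all genes, but under TMM neither was called with an estimated correlation (adjusted p = 0.3 and 0.26). A trend with transcript length, GC content or abundance could not be decided: the list medians differed from those of matched genes by -0.30 and -0.243, at percentiles 2.94 and 4.54 of random lists. No biological explanation was tested for this pattern.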
